A study of Arabidopsis thaliana with 27 samples.

How the data were processed

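Small RNAs were measured by sequencing in flowers, seedlings and roots of Arabidopsis thaliana. RNA was extracted with Trizol, and the libraries were sequenced at more than 1 place per the labels, which do not say where each library was run. The instrument was an Illumina Genome Analyzer II. Flowers came from plants grown on soil and seedlings from plates. The labels describe no protocol for heat or drought. The mRNAs of the mutated genes are not measured by small RNA sequencing and were not analysed here.

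The authors deposited 1 file per library, with each distinct sequence and its read count. The values are counts, deposited as whole numbers of at least 1 and not normalized. Sequences were 18 to 34 nt long, and 0 sequences were listed more than once in a file. Adapter trimming and any filter on reads are not stated. The submitters' notes name TAIR9 as the genome build, and an aligner is not given in the sources used here. Reads that do not match the genome are still in the files, so every read was used for the library size. All 27 libraries were used.

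Positions were computed anew by exact match of each distinct sequence to both strands of the TAIR10.1 assembly. A sequence was put in the first class that any of its matches met, in the order rRNA, tRNA, snRNA and snoRNA, chloroplast, mitochondrion, MIR gene, TAS gene, other nuclear and no match. The nuclear rRNA class took in 4000 nt on either side of the annotated genes. Named small RNAs were 123 mature miRNA sequences or passenger strands, counted as the exact sequence, and the 21-nt reads of 4 TAS families. A miRNA sequence was used only if it matched the genome in an annotated MIR gene or within 200 nt of one, which all 123 did. Identical sequences from several loci were 1 feature, named by its range (miR156a-f), so reads shared by such loci were not divided. Length variants, used as an alternative, were sequences of 19 to 24 nt that share the first 18 nt. Distinct tags of 18 to 28 nt were also tested without regard to annotation.

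Libraries held 1954060 to 12306066 reads and 164302497 in all. They held 196715 to 3377597 distinct tags, of which 69.1% to 94.9% were seen as 1 read. A count of 0 allows up to 3 reads, or 0.244 to 1.54 RPM per library, and folds against a group at 0 use this floor in each library. Replicate libraries differed by more than counting error, with a mean chi-square per feature of 311 to 17426 (near 1 if only counting error acted), and correlated at r = 0.744 to 0.926 over log2 counts of features, which are not independent replicates. Intervals and floors cover counting error only.

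Groups followed the labels' genotype, tissue and treatment. Named small RNAs and tags were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3). A feature or tag was tested with at least 10 reads in at least 2 libraries of the fit. P-values were adjusted by Benjamini-Hochberg over the features of a comparison, with a threshold of 0.05, and counts adjusted over a list alone used the list's p-values only. The SE of a log2 fold change is its size divided by the square root of the F statistic. The 4 flower genotypes were fitted together with all reads as the library size, since the mutants lack whole classes of small RNA. On this scale a loss of 24-nt reads by itself raises the values of the other small RNAs. Results under TMM are therefore given beside it. The rdr2 flower stress series, the rdr2 seedling series, the tissue comparison and the salt by tissue interaction each had a fit of their own with TMM factors over the features tested. Each seedling stress was set against all 3 untreated libraries. In fits with groups of 1 library, that library was assumed to vary like the replicated groups. Flower libraries with equal replicate numbers deviated together from their genotype means, with r = 0.332 to 0.783 over named small RNAs and 0.551 to 0.773 over 24-nt tags in all 6 pairs of genotypes (features are not independent replicates). The pairing of equal numbers comes from this correlation only, since the labels name no shared batch, and a fit with a replicate block is given beside results whose call or count it changed. A share of reads was compared between all 8 rdr2 and all 4 wild-type flower libraries by an exact permutation test, two-sided. Pairs of 1 library each were compared as ratios of RPM with 95% intervals from the conditional exact binomial test (scipy 1.17.1), for features with at least 50 reads in 1 of the 2 libraries. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

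Comparisons, tests, 13 lists of small RNAs and the rule for naming features were fixed before the data were examined. In each fit the text names, first, the 10 features with the largest absolute log2 fold change among those that passed with every library of 1 arm above every library of the other. It also names tested members of the lists fixed for the comparison, or the 4 with the most reads where a list has more than 8. For a pair of libraries it names the 5 largest rises and 5 largest falls whose interval leaves out 1, plus the lists, and of tags the 3 largest rises and falls. Where a list's members are many, the text gives its count and median and some members. The lists hold conserved miRNAs (in families shared across land plants), phosphate, copper, sulfate, stress-survey and low-oxygen miRNAs, young miRNAs made by DCL4, triggers of secondary siRNAs, and miRNAs tied to DCL1, AGO1 or AGO2 transcripts. The others hold miRNAs of the juvenile to adult change, a pollen miRNA, passenger strands and the TAS families.

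The fits were tested on simulated data with the fitted spread, in 20 draws per comparison of named small RNAs and 1 draw per setting for tags. Libraries were drawn independently, without the shared deviation of equally numbered flower libraries, so the rates do not cover it. Of features changed 4-fold and 64-fold, 3% and 52% were recovered in the dcl1-7 comparison, and 8 of 161 calls were false. At 64-fold the share was 58% for dcl234, 53% for rdr2, 81% for salt in flowers, 31% to 47% for the other flower and seedling comparisons with 1 treated library, 73% for salt in seedlings, 62% between tissues and 29% for the interaction. Of rdr2 tags changed 64-fold, 49.3% were recovered when many tags changed and 0 when 50 tags changed by each fold. Between tissues 5.88% and 0 of such tags were recovered.

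Alternatives were TMM or all reads or reads of 18 to 22 nt as the scale, DESeq2 1.42.0 (Wald test, own size factors, no independent filtering), no low-count filter, length variants counted in, other minimum counts, each replicate left out in turn, and other sets of control libraries. Leaving out the phosphate pair, the replicate number as a block together with TMM, rRNA reads as the scale, and shares over genome-matched reads or without the wild-type submergence pair's control were chosen after seeing the data. Outlier tests and random regroupings of samples were not run, since no group has more than 3 libraries.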

Results

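The data are 27 small RNA libraries of Arabidopsis thaliana, each given as the read count of every distinct sequence of 18 to 34 nt. They fall into 19 groups by genotype, tissue and treatment. Untreated flowers gave 2 libraries each of wild type, dcl1-7, dcl234 and rdr2. The dcl1-7 allele weakens DICER-LIKE 1 (DCL1), the enzyme that cuts most miRNAs. The dcl234 plants lack DCL2, DCL3 and DCL4, which cut siRNAs of 22, 24 and 21 nt. The rdr2 plants lack RNA-DEPENDENT RNA POLYMERASE 2, which makes the precursors of 24-nt siRNAs. Flowers of rdr2 were also taken under salt (2 libraries), submergence, salt with submergence, cold and drought (1 each). Seedlings of rdr2 gave 3 untreated libraries, 2 under salt, and 1 each under heat, submergence, salt with submergence and phosphate starvation. Wild type gave 1 submerged flower library with 1 control, and 1 nickel-treated root library with 1 control.

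Libraries held 1954060 to 12306066 reads, with a median of 5677380. The wild-type flower libraries held 4204455 and 6963781 reads, dcl1-7 held 5989132 and 6199680, dcl234 held 3737661 and 6213407, and rdr2 flowers held 5518093 and 5994423. Untreated rdr2 seedlings ranged from 2539812 to 6434882 reads. The wild-type submergence pair held 12306066 (control) and 11757131 reads, and the root pair 1954060 (control) and 2064719. In 25 libraries 71.1% to 88.7% of reads matched the genome exactly. In the phosphate-starved seedlings the share was 29.9%, and in the untreated library taken as their control 22%. Abundances below are RPM (reads scaled to 1000000 reads of the library), as mean ± SD where a group has replicates. Groups of 1 library have no replicate check, and in the fits they were assumed to vary like the replicated groups. The labels do not say whether replicate libraries come from separate plants, so the p-values measure the spread between libraries, which may be technical.

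The first question was which length classes depend on RDR2. Reads of 24 nt made up 8.0% ± 1.89 (SD, n = 8) of rdr2 flower libraries and 63.0% ± 8.62 (n = 4) of wild-type flower libraries. The difference was −55.0 percentage points (exact permutation test, two-sided, p = 0.00202, the smallest that the splits allow). Reads of 21 nt made up 42.0% ± 6.80 (n = 8) and 6.56% ± 4.81 (n = 4), a difference of 35.5 points (exact permutation test, two-sided, p = 0.00202). All 8 rdr2 libraries lay outside the wild-type range for both lengths. Shares are parts of a whole, so a loss of 24-nt reads by itself raises the shares of other lengths. The 21-nt difference is therefore no separate evidence that 21-nt small RNAs rose. Without the stressed libraries and the wild-type submergence control the differences were −47.9 and 29.3 points. The 2 libraries against 2 that remain allow no exact permutation p under 0.333. In dcl234 flowers the 24-nt share was 8.58% and 7.45%, while in dcl1-7 flowers it was 47.2% and 57.0%, beside 51.1% and 63.2% in untreated wild type. Wild-type roots held 40.0% of 24-nt reads without nickel and 32.4% with it. The 95% Wilson intervals of these shares were no wider than 0.2 points, and they cover counting error only.

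**Figure D1:**
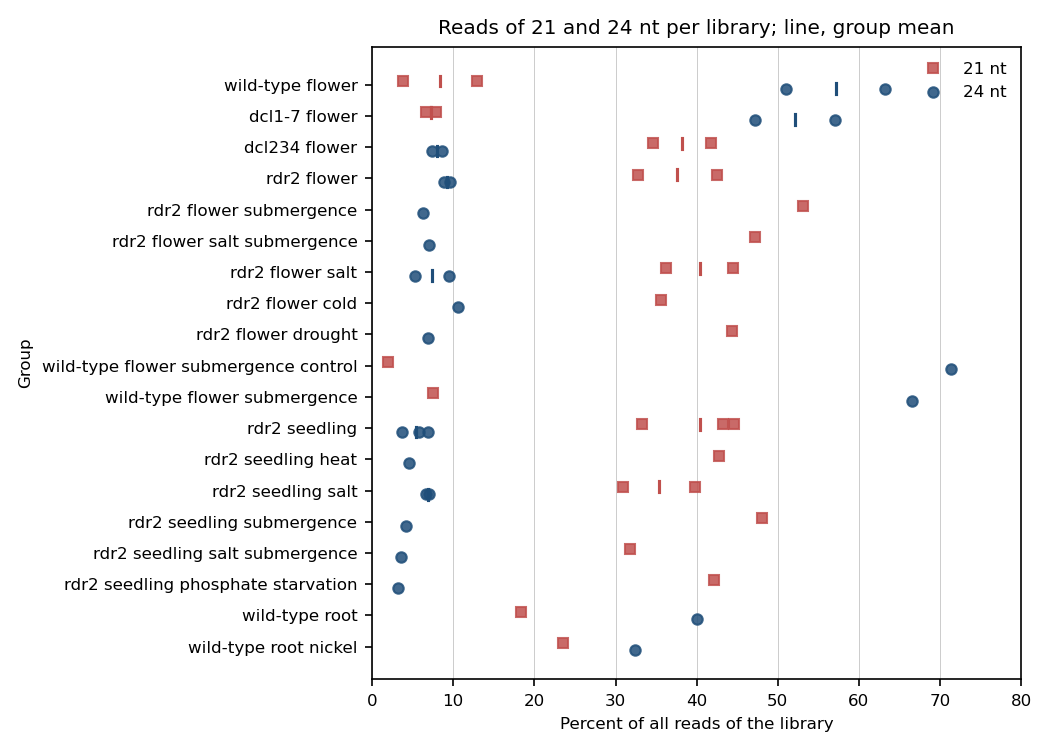
Percent of reads that are 21 nt and 24 nt long in each of the 27 libraries, by group. Each point is 1 library and each line a group mean. The 8 rdr2 flower libraries lie between 5.25% and 10.6% for 24 nt, below the 51.1% to 71.3% of the 4 wild-type flower libraries.

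In dcl1-7 flowers, the trans-acting siRNAs of TAS1 and TAS2 fell, and so did several miRNAs. miR173 cleaves TAS1 and TAS2 transcripts, which are then turned into 21-nt trans-acting siRNAs. It was at 2.75 ± 2.95 against 1289 ± 1789 RPM in wild type (n = 2 each; log2 fold change −8.86, SE 2.28, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0335; MIR173, AT3G23125, chromosome 3, 8236161 to 8236182, TAIR10.1). Wild-type libraries 1 and 2 held 2554 and 24.0 RPM of it, and without library 1 the value was −3.11 and no longer passed. The 21-nt siRNAs of TAS1 fell to 14 ± 1.40 against 1764 ± 158 RPM (−6.97, SE 1.46) and those of TAS2 to 2.46 ± 0.0601 against 452 ± 201 RPM (−7.51, SE 1.53), both with an edgeR Benjamini-Hochberg adjusted p of 0.0213, and without wild-type library 1 at −6.88 and −6.96. TAS3 siRNAs, which miR390 sets off from other transcripts, were at 599 ± 186 against 953 ± 585 RPM (−0.67, SE 1.06) and did not pass, and under trimmed-mean (TMM) scaling their change had the other sign (0.72). DESeq2 called them higher. Among the miRNAs, miR158a fell to 61.8 ± 48.6 against 17671 ± 19202 RPM (−8.16, SE 1.91; AT3G10745, chromosome 3, 3366349 to 3366368), miR167a-b to 101 ± 43.4 against 9107 ± 8729 RPM (−6.50, SE 1.73) and miR780 to 4.96 ± 2.91 against 228 ± 42.5 RPM (−5.52, SE 1.31), and the smallest falls with 1 wild-type library left out were −6.05, −4.87 and −5.32. miR827 had 0 reads in dcl1-7 and 5.14 ± 4.84 RPM in wild type, at least 10.4-fold lower with 3 reads per library as the floor (3.50-fold without wild-type library 2).

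In all, 12 of 90 small RNAs fell in dcl1-7 and 0 rose, and 31 had an unadjusted p under 0.05. The others that fell were miR158b (−6.95), miR163 (−6.40), miR403 (−5.54), miR447a-b (−5.29) and miR775 (−4.71), the last 2 named after their values were seen. Of 29 conserved miRNAs tested 1 fell (0 adjusted over the list alone), and of 5 miRNAs that set off secondary siRNAs 1 fell (1 adjusted over the list alone). Of 3 miRNAs tied to the DCL1, AGO1 or AGO2 transcripts 1 fell (2 adjusted over the list alone: miR403 and miR162a-b, −3.72). miR168a-b, which targets AGO1, was at 2070 ± 155 against 1786 ± 2125 RPM (0.21, and −0.67 without wild-type library 2). Wild-type libraries 1 and 2 held 22900 and 1188 reads of it and the dcl1-7 libraries 12156 and 13054. Its direction thus depends on which wild-type library is taken, and it stood far above library 2. None of 9 passenger strands, 2 young miRNAs made by DCL4 or the pollen miRNA miR845a changed, over all features or adjusted over the list alone. With 1 library left out the list calls moved. The conserved list alone gave 8 and the passenger strands and miR845a 1 each without wild-type library 2, and the conserved list 1 without wild-type library 1. The trigger list gave 0 without wild-type library 1 or dcl1-7 library 2, and the list tied to DCL1 and AGO transcripts gave 0 without either dcl1-7 library and 1 without wild-type library 2. The count of 12 became 0 without either dcl1-7 library, 10 without wild-type library 1, 28 without wild-type library 2, 0 under TMM, and 25 (13 higher, 12 lower) in DESeq2. With a replicate block it was 22 (1 higher, 21 lower), with miR162a-b (−3.63), 3 conserved miRNAs (2 adjusted over the list alone) and 1 passenger strand (1) among them. The share of features with a higher estimate was 11.1%, against 41.6% without wild-type library 1, 36.7% under TMM and 48.9% in DESeq2. The median log2 fold change of all features was −2.63, −0.35 without wild-type library 1 and −1.12 under TMM.

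**Figure D2:**
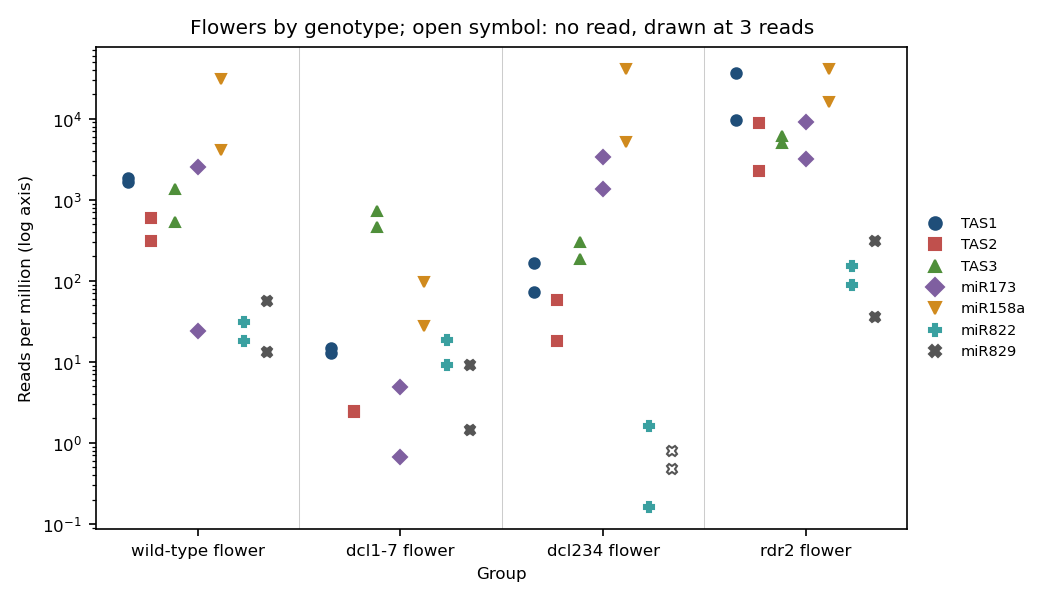
RPM (log axis) of the 21-nt siRNAs of TAS1, TAS2 and TAS3 and of miR173, miR158a, miR822 and miR829 in flowers of wild type, dcl1-7, dcl234 and rdr2. Each point is 1 library (n = 2 per genotype), open symbols stand for 0 reads and are drawn at 3 reads. TAS1 siRNAs averaged 1764 RPM in wild type, 14 in dcl1-7, 120.3 in dcl234 and 23262 in rdr2.

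In dcl234 flowers the comparison asks what is lost with the siRNA-making Dicers. Over all 90 features edgeR called 0, with 15 at an unadjusted p under 0.05, and DESeq2 called 8 (2 higher, 6 lower). With a replicate block 9 were called (4 higher, 5 lower), among them miR822 (−5.10), miR839, miR829, TAS1 (−4.04) and TAS2 (−3.89). Adjusted over the list alone, 2 of 2 young miRNAs known to be made by DCL4 fell. Without dcl234 library 1 this no longer held for miR839, and without library 2 it held for neither. miR822 was at 0.883 ± 1.02 against 24.5 ± 9.05 RPM (−4.82, SE 1.53; AT5G03552, chromosome 5, 897287 to 897307), and miR839 had 0 reads against 2.69 ± 1.57 RPM, at least 4.19-fold lower (2.46-fold without wild-type library 2, AT1G67481, chromosome 1, 25279138 to 25279158). TAS1 siRNAs at 120.3 ± 67.5 against 1764 ± 158 RPM (−3.87, SE 1.26) and TAS2 siRNAs at 37.8 ± 28.1 against 452 ± 201 RPM (−3.58, SE 1.27) fell adjusted over the list alone, and TAS3 (−1.96) did not. The TAS list gave 0 without either dcl234 library or wild-type library 1. miR173 itself was at 2356 ± 1387 against 1289 ± 1789 RPM (0.87, and −0.12 without wild-type library 2). Wild-type libraries 1 and 2 held 17789 and 101 reads of it and the dcl234 libraries 12471 and 8543. In dcl234 it thus stood near wild-type library 1 and far above library 2. A further 24-nt miRNA named after its values were seen, miR829, had 0 reads against 34.7 ± 30.2 RPM (at least 54.1-fold lower, or 20.8-fold without wild-type library 2; AT1G32713, chromosome 1, 11834094 to 11834117). None of 29 conserved miRNAs, 5 triggers, 3 miRNAs tied to DCL1 or AGO transcripts, 9 passenger strands or miR845a was called, also adjusted over the list alone, but without wild-type library 1 the lists alone gave 7 conserved miRNAs and 3 triggers higher. The conserved list had a median log2 fold change of 1.69, 3.42 without that library and −0.05 under TMM. Estimates were higher for 88.9% of features, against 53.3% under TMM, 60.0% scaled to reads of 18 to 22 nt and 56.7% in DESeq2. The count was 14 (12 higher, 2 lower) without wild-type library 1, 2 without wild-type library 2, 4 lower under TMM and 5 with the 18 to 22 nt scaling.

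In rdr2 flowers the trans-acting siRNAs stood above wild type, as did most features. TAS1 siRNAs were at 23262 ± 19302 against 1764 ± 158 RPM (3.72, SE 1.25), TAS2 at 5584 ± 4721 against 452 ± 201 RPM (3.63, SE 1.27) and TAS3 at 5582 ± 783 against 953 ± 585 RPM (2.55, SE 1.12). All 3 rose adjusted over the list alone, and none did over all 90 features (edgeR, Benjamini-Hochberg adjusted p from 0.188 to 0.238, higher in 2 of 2 libraries). The median of the 3 was 3.63, and 1.65 under TMM. Library 1 held 9614 and 2245 RPM of TAS1 and TAS2. Without library 2 the values were 2.45, 2.31 and 2.40, beside a median of 2.31 over all features, and the list gave 0, as it did without either wild-type library. The pollen miRNA miR845a, a list of its own, was at 22.1 ± 19.5 against 1.82 ± 1.90 RPM (3.56, SE 1.55, and 2.16 without rdr2 library 2). Over all features edgeR called 0, with 17 at an unadjusted p under 0.05, and DESeq2 called 1 higher. The 29 conserved miRNAs (median 2.12), 5 triggers, 3 miRNAs tied to DCL1 or AGO transcripts and 9 passenger strands gave 0, also adjusted over the list alone. Estimates were higher for 97.8% of features, against 65.6% under TMM, 73.3% with the 18 to 22 nt scaling and 58.9% in DESeq2, and the median moved from 2.28 to 0.55 under TMM. Without wild-type library 1 the count was 15, all higher, and the lists alone gave 10 conserved miRNAs, 2 triggers and 3 passenger strands higher. Without rdr2 library 1 they gave 1 passenger strand. With a replicate block it was 3, all higher, and the lists alone gave 4 conserved miRNAs, 2 triggers and 1 passenger strand higher, but not miR845a (3.17).

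Over all abundant sequences, 88074 tags were tested in the flower genotypes. In rdr2, 53117 tags changed, 51402 lower and 1715 higher (edgeR, Benjamini-Hochberg). Of the 46335 tags of 24 nt tested 85.6% were lower, and tags of 24 nt made up 77.2% of those lower. The largest falls among tags of 1 genome position were AGAGTACGAAGACGACTGATCATA, in a coding exon of AT2G02440 (chromosome 2, 639274 to 639297; 0 reads against 144 ± 63.9 RPM, at least 277-fold lower), and AGGATATGGCATGAGAGCGAAGAT, in a coding exon of AT3G23650 (chromosome 3, 8511183 to 8511206; 0 reads against 143 ± 12.9 RPM, at least 274-fold lower). AGGGCTTATTGGATCTAAAGACGG, with 47 genome matches, was at least 351-fold lower, or 76.5-fold without wild-type library 2. Of 578 tags in TAS loci 121 rose (20.9%) and 0 fell, beside rises of 32.1% of snRNA and snoRNA tags, 21.3% of chloroplast, 17.1% of tRNA and 14.8% of MIR tags, so the rises were not confined to TAS loci. Fewer rose among other nuclear tags (0.778%), rRNA (2.08%), mitochondrial (2.78%) and unmatched tags (4.80%). The largest rises were 2 tags of 21 nt without a genome match, held almost wholly by rdr2 library 2 (0 and 0.167 RPM in library 1, 322 and 955 RPM in library 2), and the tRNA tag GTGGCTGTAGTTTAGTGGTAAGAA, with 0 reads in wild type and 58.2 ± 80.4 RPM in rdr2 (at least 102-fold higher, or 2.33-fold without rdr2 library 2).

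In dcl234, 23130 tags changed, 21342 lower and 1788 higher, and 51416 (44118 lower, 7298 higher) with a replicate block. Tags of 24 nt made up 87.1% of those lower, and tags of 21 nt 73.0% of those higher. In TAS loci 79 of 578 tags fell (13.7%) and 3 rose, beside falls of 33.9% of other nuclear tags and 5.78% of MIR tags. ACGACGAGAACATGATCAAGCGAA, between AT1G13195 and AT1G13200 (chromosome 1, 4505958 to 4505981), had 0 reads against 96.6 ± 38.3 RPM, at least 150.3-fold lower. TTTGCGACGACAACAGAACACAGT (39 matches) and TTTGCGACGACAGCAGAACACAGT (38 matches) were at least 123-fold and 105-fold lower. Higher were a 23-nt tag without a genome match (21.9 and 81.1 RPM in dcl234 libraries 1 and 2), GAATGACACATGTAAACATCTGATCGT (21 matches, at least 64.9-fold, or 28.1-fold without dcl234 library 2) and GATAGACAAGGTAGGAGAAAATGACTC, which lies antisense in TAS3 (AT3G17185, chromosome 3, 5862325 to 5862351; 34.4 ± 38.1 RPM against 0 reads, at least 60.1-fold, or 13.1-fold without dcl234 library 2). Both counts were 0 without either of the mutant's own libraries. In dcl1-7 edgeR called 0 tags, with 3285 at an unadjusted p under 0.05, DESeq2 called 170 (6 higher, 164 lower), and a replicate block gave 1774 (747 higher, 1027 lower).

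The stress series in rdr2 flowers asks which miRNAs respond where 24-nt siRNAs are few. Salt was given as 0.1 or 0.3 M NaCl for 24 h, and the labels do not say which dose a library had. None of the 104 small RNAs passed in edgeR under salt, submergence, salt with submergence, cold or drought, with 2, 2, 2, 1 and 3 at an unadjusted p under 0.05. DESeq2 called 1, 1 and 1 lower, 0 and 0. The lowest unadjusted p in each comparison fell on miR867, which stood at 9.34 and 160.2 RPM in untreated libraries 1 and 2, and without library 2 its unadjusted p lay between 0.299 and 0.511. Estimates that were higher made up 57.7%, 47.1%, 45.2%, 44.2% and 51.9% of features in the 5 comparisons, and 68.3%, 70.2%, 66.3%, 54.8% and 67.3% when scaled to all reads.

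None of the copper miRNAs, which silence copper proteins, passed under any of these stresses, and the stresses were not tested against each other. Under drought, miR398b-c was at 8.75 against 0.174 ± 0.0102 RPM (4.84, SE 2.05, unadjusted p = 0.0287, edgeR with Benjamini-Hochberg adjusted p = 0.941), miR397a at 25.8 against 1.85 ± 0.968 RPM (2.90) and miR857 at 17.0 against 2.34 ± 0.232 RPM (2.10). Under submergence, miR397a was at 0.219 against 1.85 ± 0.968 RPM (−4.15), miR857 at 0.329 against 2.34 ± 0.232 RPM (−3.80) and miR408 at 11.5 against 52.3 ± 68.3 RPM (−3.59, and 0.85 without untreated library 2). The medians of the 5 tested copper miRNAs were 1.39 under salt, −3.59 under submergence, −1.88 under salt with submergence, 2.01 under cold and 2.10 under drought, with the same signs when scaled to all reads. The salt libraries went opposite ways. Library 1 held 95, 519, 14 and 39 reads of miR397a, miR397b, miR398b-c and miR857, library 2 held 0 of each, and without library 1 the salt median was −7.79 over 4 tested, from fitted values that are no bound.

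Under cold, miR169h-n was at 445 against 99.8 ± 100.4 RPM (2.17) and miR402 at 35.4 against 9.46 ± 9.03 RPM (1.89). Under salt, the sulfate miRNAs miR395a-d-e (10.2 ± 8.46 against 2.19 ± 0.743 RPM, 1.47) and miR395b-c-f (1.30) lay higher, while miR408 was at 11.8 ± 9.72 against 52.3 ± 68.3 RPM (−2.98, and 1.46 without untreated library 2). Under salt with submergence, miR399b-c was at 52.4 against 6.06 ± 3.70 RPM (2.43). Called over all features and adjusted over the list alone, the counts were 0 for every list fixed for these comparisons, except that miR398b-c rose over the copper list alone in drought when scaled to all reads or to reads of 18 to 22 nt. These were 30 conserved and 5 copper miRNAs in all 5, 6 phosphate miRNAs in salt, submergence and both, 2 sulfate miRNAs in salt and both, 8 miRNAs from surveys of cold, drought and salt in all but submergence, and 5 miRNAs from surveys of low oxygen in submergence and both. The 5 low-oxygen miRNAs had a median of −0.07 under submergence, and 0.64 when scaled to all reads. Among them, miR158a was at −0.79 and miR391 at −0.07. Without untreated library 2 the value of miR158a was 0.62, and without library 1 that of miR391 was 2.82.

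**Figure D3:**
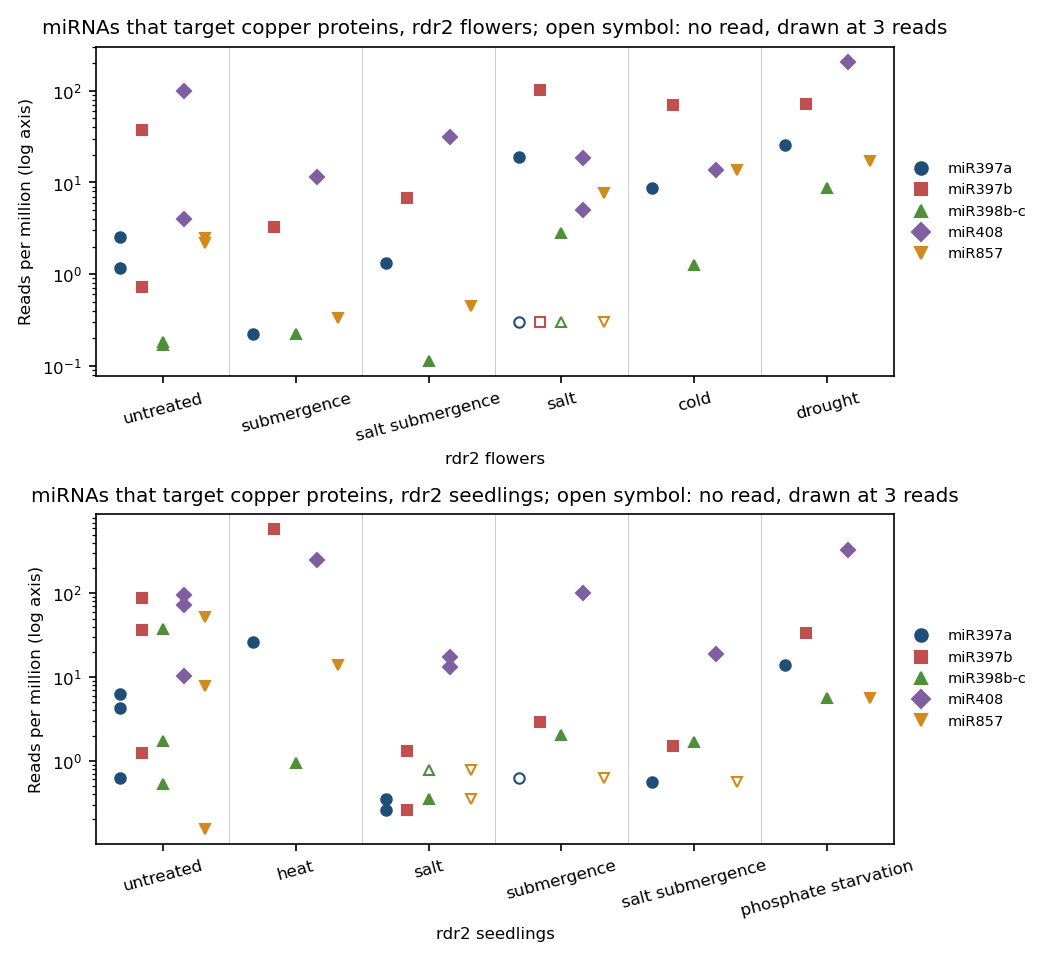
RPM (log axis) of miR397a, miR397b, miR398b-c, miR408 and miR857 in rdr2 flowers (top) and rdr2 seedlings (bottom) by treatment. Each point is 1 library, open symbols stand for 0 reads and are drawn at 3 reads. In seedlings miR857 had 0 reads under salt, submergence and both, against 7.75, 0.155 and 52.8 RPM in the 3 untreated libraries.

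In rdr2 seedlings under 0.3 M NaCl for 8 h, 1 copper miRNA passed over all features. miR857 had 0 reads in 2 of 2 salt libraries against 20.2 ± 28.4 RPM (n = 3), at least 35.6-fold lower (SE 2.96 of the log2 change, edgeR, Benjamini-Hochberg adjusted p = 0.0344; AT4G13554, chromosome 4, 7878198 to 7878218). The untreated libraries held 7.75, 0.155 and 52.8 RPM, and without library 3 the bound was 6.96-fold. It was the only 1 of 90 features that passed (6 at an unadjusted p under 0.05; DESeq2 called 2). That call became 0 without any 1 of the 5 libraries compared, and 0 when scaled to all reads or to reads of 18 to 22 nt or set against libraries 1 and 2 only, the controls named for salt. Adjusted over the list alone, 3 of 5 copper miRNAs fell, but 2 without untreated library 3 (miR857 and miR397b) and 0 without either salt library. miR397b was at 0.780 ± 0.735 against 41.8 ± 43.6 RPM (−5.97, SE 2.03) and miR398b-c at 0.177 ± 0.251 against 13.2 ± 21.0 RPM (−6.64, SE 2.25; 37.4 RPM of it in untreated library 3, and −6.64 became −2.31 without that library). miR397a (−3.66) and miR408 (15.4 ± 2.90 against 59.0 ± 43.6 RPM, −1.49) did not pass. Untreated library 2 held 1 read of miR857 and 8 of miR397b (0.155 and 1.24 RPM), and salt library 2 held 0 and 11 (1.30 RPM of miR397b), so these falls rest on untreated libraries 1 and 3. The 29 conserved, 7 phosphate, 2 sulfate and 7 stress-survey miRNAs gave 0, also adjusted over the list alone.

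Submergence for 8 h and its combination with salt also left miR857 at 0 reads. The single submerged library was at least 32.7-fold below the untreated mean and the combined one at least 36.0-fold, or 6.38-fold and 7.04-fold without untreated library 3. miR397a had 0 reads in the submerged library, at least 6.0-fold lower, or 3.92-fold without library 3. Untreated library 2, the control named for submergence and salt, held 1 read of miR857 and 4 of miR397a, so against it no fall of either was detectable at this depth. Adjusted over the list alone, 2 and 1 copper miRNAs fell (miR857 in both, and miR397a under submergence), and 0 in both when scaled to all reads. Without untreated library 1 the counts were 1 and 0, without library 2 they were 1 and 1, and without library 3 they were 3 and 2. Over all 90 features edgeR called 0 in both, with 4 and 2 at an unadjusted p under 0.05, and DESeq2 called 0 and 1. The conserved, phosphate, low-oxygen and, in the combined stress, sulfate and stress-survey lists gave 0, also adjusted over the list alone. Phosphate miRNAs had a median of 1.19 under submergence and −0.61 in the combination (0.03 when scaled to all reads). Estimates were higher for 41.1% and 38.9% of features, and for 74.4% and 60.0% when scaled to all reads.

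Under heat, the largest rises by estimate lay on miR169d-g and the flowering-time miRNA miR172c-d, named after their values were seen. miR169d-g was at 1633 RPM against 28 to 58.7 in the 3 untreated libraries (4.47, SE 1.63, unadjusted p = 0.00665, edgeR with Benjamini-Hochberg adjusted p = 0.584), and miR172c-d at 294 against 11.9 ± 9.56 RPM (3.96). miR824 was at 2581 against 159 ± 128 RPM (3.33). Of the copper miRNAs, miR397b was at 582 against 41.8 ± 43.6 RPM (2.89) and miR398b-c at 0.932 against 13.2 ± 21.0 RPM (−4.98). Untreated library 3 held 37.4 RPM of miR398b-c and library 1, the control named for heat, 0.528 RPM, and the value was −0.69 without library 3 and 0.02 against library 1. miR393a-b was at 21.7 against 3.20 ± 2.27 RPM (2.14). Over all 90 features edgeR called 0, with 6 at an unadjusted p under 0.05, and DESeq2 called 3 (1 higher, 2 lower). The 29 conserved, 5 copper and 7 stress-survey miRNAs gave 0, also adjusted over the list alone. Estimates were higher for 40.0% of features and for 52.2% when scaled to all reads.

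In the single phosphate-starved library, 4 of 7 miRNAs known to rise in phosphate-starved plants passed as higher. miR399f was at 5197 against 12 ± 4.20 RPM in untreated seedlings (n = 1 and 3; 7.85, SE 1.79, edgeR, Benjamini-Hochberg adjusted p = 0.00146; AT2G34208, chromosome 2, 14445084 to 14445104). miR399d was at 905 against 2.56 ± 1.09 RPM (7.59, SE 1.89; AT2G34202, chromosome 2, 14442988 to 14443008). miR827 was at 3818 against 22.4 ± 21.7 RPM (6.47, SE 1.71; AT3G59884, chromosome 3, 22122811 to 22122831), and the passenger strand miR399c-star at 148 against 0.843 ± 0.717 RPM (6.44, SE 1.94; AT5G62162, chromosome 5, 24962497 to 24962517). These 4 were the only calls among 90 features (13 at an unadjusted p under 0.05; DESeq2 called 17, 13 higher and 4 lower). Adjusted over the phosphate list alone 6 rose (4 to 7 with 1 untreated library left out), which added miR399a (170.5 against 6.02 ± 4.07 RPM, 4.07) and miR2111a-b (217 against 7.11 ± 3.02 RPM, 3.92). miR399b-c was at 224 against 14.7 ± 1.45 RPM (2.99). TAS4 siRNAs, named after their values were seen, were at 1183 against 22.4 ± 8.18 RPM (4.79, edgeR with Benjamini-Hochberg adjusted p = 0.0862). Of 29 conserved miRNAs 0 changed, also adjusted over the list alone, with a median of −2.22 (−1.23 scaled to all reads). The count was 4 without untreated library 1, 0 without library 2 and 6 without library 3. Library 3, the control named for this stress, shares the low genome match of the starved library.

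**Figure D4:**
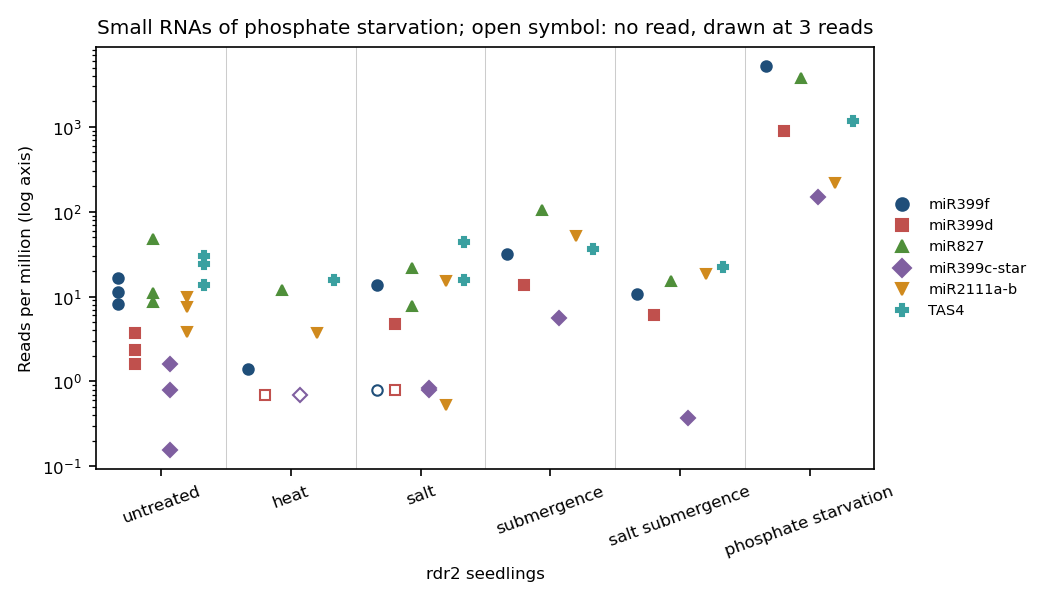
RPM (log axis) of miR399f, miR399d, miR827, miR399c-star, miR2111a-b and TAS4 siRNAs in rdr2 seedlings by treatment. Each point is 1 library, open symbols stand for 0 reads and are drawn at 3 reads. miR399f stood at 5197 RPM under phosphate starvation and at 12 ± 4.20 RPM in the 3 untreated libraries.

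Between tissues, untreated rdr2 seedlings and flowers differed in 10 of 97 small RNAs, 5 higher and 5 lower in seedlings (27 at an unadjusted p under 0.05). Flowers came from plants of 6 weeks on soil and seedlings of 2 weeks from plates. Tissue, plant age and growth medium therefore cannot be separated. miR172c-d, which promotes the adult phase and flower identity, was at 11.9 ± 9.56 against 4520 ± 4196 RPM (n = 3 and 2; −6.49, SE 1.67, edgeR, Benjamini-Hochberg adjusted p = 0.0383). miR780 was at 0.162 ± 0.156 against 669 ± 84.1 RPM (−10.09, SE 1.58; AT4G14811, chromosome 4, 8504166 to 8504186). miR867 had 0 reads in seedlings, at least 117-fold lower than the 9.34 and 160.2 RPM of flower libraries 1 and 2, or 12.9-fold without library 2. So did miR851, at least 12.5-fold lower, or 8.25-fold without flower library 1, and miR771 fell too (−6.86). Higher in seedlings was miR167c, at 5.81 ± 2.13 RPM against 0 reads in flowers, at least 11.1-fold (AT3G04765, chromosome 3, 1306750 to 1306770). The others were miR841a (7.34), miR156a-star (17.0 ± 8.24 against 0.341 ± 0.226 RPM, 7.17), miR399f (5.41) and miR399a (5.34). The juvenile miRNAs miR156a-f (144309 ± 125332 against 8257 ± 2800 RPM, 6.01) and miR157a-c (122860 ± 116973 against 5227 ± 56.6 RPM, 6.56) did not pass. Untreated seedling library 3 held 539 and 1905 RPM of them, and without it both rose adjusted over the list alone.

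Of 5 miRNAs of the juvenile to adult change 1 fell in seedlings (1 adjusted over the list alone, 0 without seedling library 2), of 29 conserved miRNAs 1 fell (0 adjusted over the list alone), and of 5 copper miRNAs 0 changed (1 adjusted over the list alone, miR398b-c, 7.14, but 0 without seedling library 3 or flower library 2). Of 4 TAS families 0 changed (1 adjusted over the list alone, TAS4, 22.4 ± 8.18 against 0.815 ± 1.15 RPM, 6.11, but 0 without flower library 1), and miR845a did not (−1.82). The count of 10 was 0 without flower library 1, 1 without flower library 2 and 19 (14 higher, 5 lower) without seedling library 3. It was 17 (4 higher, 13 lower) when scaled to all reads and 33 (16 higher, 17 lower) in DESeq2. Estimates were higher for 68.0% of features and for 43.3% when scaled to all reads. Over 28044 tags edgeR called 0, with 1637 at an unadjusted p under 0.05, and DESeq2 called 140 (83 higher, 57 lower).

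Whether salt acts differently in flowers and seedlings was tested as an interaction over 105 features. Adjusted over the list alone, 3 of 5 copper miRNAs differed. The log2 salt change in flowers minus that in seedlings was 11.46 (SE 3.94) for miR857, 8.33 (2.94) for miR398b-c and 7.69 (3.20) for miR397b. For miR857 the parts were 0.55 in flowers and −10.9 in seedlings, where neither salt library had a read of it. Where a library has no read these sizes come from fitted values that are no bound. The call of the 3 rests on single libraries. Flower salt library 1 held 39, 14 and 519 reads of the 3, and flower salt library 2 held 0 of each. Over the list alone the count was 0 without flower salt library 1 (−3.02 for miR397b), without seedling salt library 2 or without untreated seedling library 3. Over all features edgeR called 0, with 7 at an unadjusted p under 0.05, and DESeq2 called 0. Without untreated seedling library 1 the count was 3. The 30 conserved, 7 phosphate, 2 sulfate and 8 stress-survey miRNAs gave 0, also adjusted over the list alone. Flowers and seedlings had salt for 24 h and 8 h, and the flower dose was 0.1 or 0.3 M against 0.3 M, so the tissues also differed in the duration and perhaps the dose of salt. The plants differed in age and growth medium too.

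In the wild-type submergence pair, 36 of 40 small RNAs with at least 50 reads lay higher in the submerged library and 2 lower, by 95% counting intervals that leave out 1. The ratio depended on length. miR156a-f, of 20 nt, stood at 3264 against 106 RPM (ratio 30.7, 29.1 to 32.5) and miR158a, also of 20 nt, at 841 against 29.4 (ratio 28.6, 25.7 to 31.8). The 21-nt miRNAs miR167a-b (ratio 9.05), miR169b-c (8.27) and miR167a-star (10.3) came next. The only falls were the 24-nt miRNAs miR163 (ratio 0.659, 0.574 to 0.756) and miR829 (0.906, 0.831 to 0.988). All 20 conserved and 4 low-oxygen miRNAs with enough reads lay higher, among them miR159a (3.94), miR172a-b (4.29) and miR391 (5.16). The median ratio was 4.33, and 2.15 when scaled to reads of 18 to 22 nt. The control library held only 2.02% of 21-nt reads, against 7.55% in the submerged one, and the intervals compare these 2 libraries, not the conditions.

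In wild-type roots, miR846 and miR162a-b lay higher and miR852 and miR838 lower in the library given 50 µM nickel for 15 days than in its control. With at least 50 reads, 45 of 54 small RNAs had a counting interval that leaves out 1, 26 higher and 19 lower. Each condition has 1 library, so the intervals compare these 2 libraries, not the conditions. miR846 stood at 95.9 against 7.68 RPM (ratio 12.5, 7.39 to 22.7; AT1G61226, chromosome 1, 22577662 to 22577682) and miR162a-b, which targets DCL1, at 150.1 against 13.8 (ratio 10.9, 7.32 to 16.8). The next rises were miR168a-star (ratio 3.58), miR399b-c (2.89) and miR822 (2.74). miR852 fell from 53 to 2 reads (ratio 0.0357, 0.00422 to 0.136; AT4G14504, chromosome 4, 8336302 to 8336322), and miR838 (ratio 0.0568), miR396b (0.132, 62.5 against 472 RPM), miR837 (0.263) and miR2111a-b (0.308) followed. Of 21 conserved miRNAs 11 lay higher and 6 lower, with miR166a-g at a ratio of 1.74 and miR172a-b at 0.578. Of 3 phosphate miRNAs 2 lay higher, miR399b-c and miR399f (2.62), and miR2111a-b lower. The split was 20 higher and 26 lower when scaled to reads of 18 to 22 nt, and the median ratio moved from 1.14 to 0.920.

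**Figure D5:**
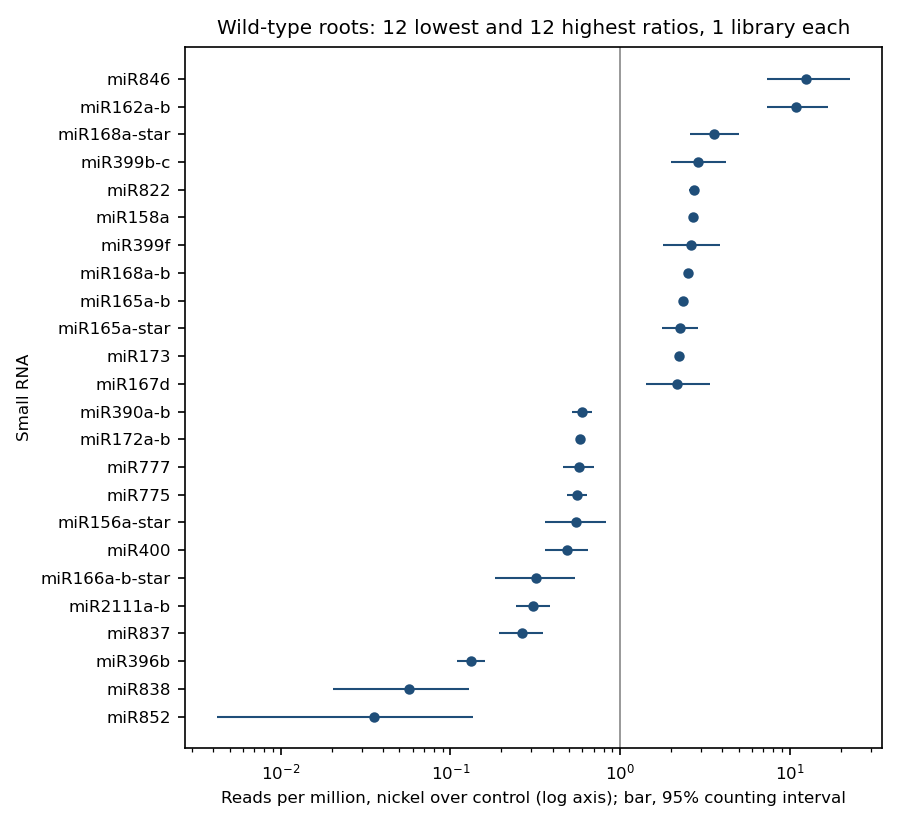
Ratio of RPM in the nickel-treated root library to the control root library (log axis) for the 12 lowest and the 12 highest of 54 small RNAs with at least 50 reads. Points are ratios and bars 95% counting intervals, from 0.0357 for miR852 to 12.5 for miR846.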

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

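Tests chosen only after the result was seen were those of read length and of non-overlapping tags in the numbered flower libraries, of length forms in the wild-type submergence pair, and all 3 on the phosphate pair.

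The salt response of 3 of 5 copper miRNAs differed between flowers and seedlings adjusted over the list alone, and that of none over all features. The log2 salt change in flowers minus that in seedlings was 11.46 for miR857, 8.33 for miR398b-c and 7.69 for miR397b. Neither seedling salt library had a read of miR857, so its size comes from fitted values that are no bound. Flower salt library 2 had 0 reads of all 3, and without flower salt library 1 the list gave 0. Flowers had salt for 24 h at 0.1 or 0.3 M and seedlings for 8 h at 0.3 M. Tissue, plant age, growth medium, duration and dose thus cannot be separated.

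Of 228 annotated mature sequences outside the list used in the report, 8 had at least 50 reads in a stressed library and at least 10 times the RPM of the highest control library. All libraries concerned are single ones, so these are values without a test. Under phosphate starvation miR2111a-3p stood at 3403 RPM (highest control 12.9) and miR2111b-3p at 170.5 RPM (14.8). Under heat in seedlings miR169a-3p stood at 294 RPM (3.15), miR156h at 183.5 RPM (11.5) and miR5648-3p at 13.7 RPM (1.18), and miR169a-3p was also at 52.0 RPM under submergence (3.15). In flowers miR408-5p stood at 4112 RPM under drought (331), and miR5020c at 8.58 RPM under salt with submergence (0.834). In roots miR829-5p stood at 921 RPM under nickel (39.4).

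Flower libraries with the same replicate number deviated from their genotype means together, at the same 24-nt tags. Among nuclear tags of 24 nt alone the correlation was at least 0.551. Recovery of lengths is thus excluded as the whole cause. It may still have a part in the deviation of named small RNAs, which differ in length. GC content is excluded as the whole cause too. The correlation between wild type and dcl1-7 was 0.746 before and 0.702 after the mean of each GC count was taken off. The deviations still went with GC. From 6 to 15 GC bases, the mean log2 ratio of library 1 to library 2 rose from −2.47 to 1.28 in wild type. In dcl1-7 it rose from −2.30 to 1.235. Plants that differed at whole loci would move neighbouring tags together, but 24-nt tags of 1 locus that start 24 to 200 nt apart correlated at only 0.0489. The bound set beforehand, on tags 1 nt apart (0.738), was wrong as a test of loci, because such tags share nearly all of their sequence. The correlation fell from 0.736 at 1 nt to 0.405 at 5 nt and 0.088 at 24 nt, with small rises between. Recovery of sequences during library preparation is thus a candidate explanation, and the labels give no preparation batch with which to test it.

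In the phosphate-starved seedlings and their control most reads missed the genome. Of 21-nt reads at least 51.9% missed the genome in both libraries, against 7.97% to 13.3% in the other 7 rdr2 seedling libraries. Adapter behind a full small RNA of 21 nt is thus excluded as the whole cause. Adapter behind a shorter insert could also give such reads, so the test cannot exclude adapter in general. Reads of 29 to 34 nt made up 27.6% of the control and 33.5% of the starved library. Of these, 16.4% and 14.4% held an adapter start, against 18.1% to 71.0% in the other 7. Reads 1 substitution away from miR167a-b were more frequent in both libraries, at 36.1% and 20.3% of its exact reads against 6.34% to 10.1% elsewhere, and they may be errors or related sequences of another organism. Taken as an error rate this gives less than the unmatched share, by a factor of at least 2.04 against 1.05 to 1.54 elsewhere, but it counts single substitutions only, so reads with many errors stay open. Of the unmatched 21-nt reads at least 66.8% lay more than 2 substitutions from every matching tag with at least 10 reads, against 12.5% to 33.9% elsewhere. Such tags numbered only 783 in the control and 1325 in the starved library, against 1831 to 4343 elsewhere. Fewer tags to compare with can by themselves put more reads farther away. Reads of another organism are a candidate source. They cannot be told apart here from reads with many errors or with adapter behind a short insert, and no biological explanation was tested.

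In the wild-type submergence pair nearly all named small RNAs lay higher in the submerged library. Weaker recovery of short reads in the control library may explain much of this, since among rRNA reads the ratio of 21 nt to 24 nt was 3.96 times higher in the submerged library, beside a median ratio of 4.66 for named small RNAs of 21 nt. A rise of every length form of a miRNA alike is argued against, since the 24-nt forms of miRNAs of 20 and 21 nt had a median ratio of 1.06 (quartiles 0.926 to 1.47, 10 miRNAs) while the forms of 20 nt had 10.7 and those of 21 nt 5.27, although another Dicer may make the 24-nt forms. After scaling by rRNA reads of the same length the 21-nt miRNAs kept a median ratio of 2.60, but that scale takes rRNA reads to be unaffected by submergence, and their own ratio was 1.79 at 21 nt and 0.453 at 24 nt. An effect of submergence on some miRNAs stays open, since each condition has 1 library.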

How the results depend on the processing

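The phosphate pair left out, the numbering together with TMM, rRNA scaling, genome-matched shares and shares without the submergence control were alternatives chosen after the data were seen. Except where a sentence names a cause, the cause was not tested.

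The length shares kept their direction under every alternative, from −42.9 to −59.6 points for 24 nt and from 19 to 37.3 for 21 nt. With only the libraries labelled untreated, which leaves out the submergence control too, they were −47.9 and 29.3 (exact permutation p = 0.333, the smallest that 2 against 2 allow). The rdr2 and dcl234 tags fell in the main under every scaling, tool and minimum tried. dcl234 gave 31701 tags under TMM, 32804 in DESeq2, 48821 when scaled to 18 to 22 nt and 57083 with the submergence control as another wild-type library, against 23130. rdr2 gave 56156, 53905, 57986 and 84202, against 53117. With at least 50 reads they gave 5017 and 8231, since fewer tags (14831) were tested. dcl1-7 tags (0) were 170 and tissue tags (0) 140 in DESeq2, and tissue tags were 9 with at least 50 reads.

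DESeq2 counts of small RNAs, with edgeR's in brackets, were 25 (12) for dcl1-7, 8 (0) for dcl234, 1 (0) for rdr2, 1 (0) each for flower salt, submergence and both, 2 (1) for seedling salt, 3 (0) for heat, 1 (0) for seedling salt with submergence, 17 (4) for phosphate and 33 (10) between tissues. TAS3 siRNAs in dcl1-7 reversed there, at 1.65 (DESeq2, Benjamini-Hochberg adjusted p = 0.0148), against −0.67. Under TMM dcl1-7 gave 0 and dcl234 4. Scaled to 18 to 22 nt, dcl234 gave 5, seedling salt 0 and tissues 18. Scaled to all reads, seedling salt gave 0 and tissues 17. Without the low-count filter, dcl1-7 gave 22, dcl234 3, rdr2 2 and the interaction 3. With length variants, dcl234 gave 2 and seedling salt 2. With the submergence control as another wild-type library, dcl1-7 gave 3, dcl234 3 and rdr2 2, and with only the 2 genotypes compared dcl1-7 gave 2 and dcl234 2. Seedling salt gave 0 against the controls named for it and 0 without the phosphate pair. For the other seedling stresses the named control is 1 library against 1, which gives ratios and no count.

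Leaving out 1 library at a time gave 0 to 28 calls for dcl1-7, 0 to 14 for dcl234, 0 to 15 for rdr2, 0 for seedling salt, 0 to 6 for phosphate, 0 to 19 between tissues and 0 to 3 for the interaction. It gave 0 to 18631 tags for dcl234 and 0 to 45323 for rdr2, with 0 when a library of the mutant was left out, which leaves 1 library on that side, assumed to vary like the other groups. The flower stresses, heat, seedling submergence, seedling salt with submergence, dcl1-7 tags and tissue tags stayed at 0.

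With a replicate block dcl1-7 gave 22 calls (12 without it), dcl234 9 (0) and rdr2 3 (0), and the tags gave 1774 (0), 51416 (23130) and 64286 (53117). It changed no other call of a named feature than those given in the report. A replicate block with TMM gave 18, 9 and 1. Untreated and salt-treated rdr2 flowers, 2 libraries each, share only their numbers (deviations correlated at r = 0.263), and there the block gave 0 calls.

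Among the pairs of single libraries, the submergence split kept its direction and the nickel split did not. Under submergence 36 small RNAs had an interval that leaves out 1 when scaled to 18 to 22 nt (30 higher, 6 lower) and 36 when scaled by rRNA reads (32 higher, 4 lower). Under nickel 46 did when scaled to 18 to 22 nt (20 higher, 26 lower), so its balance of rises and falls depends on the scale.

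Named features gave 108 entries, each a feature in 1 comparison. Of their 953 values under alternatives, 762 stayed on the same side of the threshold, or near their value where no test was made. Of these, 16 changed sign without passing in either setting. A further 90 no longer passed, 72 passed only there, 28 moved by more than their counting interval or SE and 1 reversed. Entries that did not pass in the main setting counted as the same when they again did not pass. The 762 is therefore no measure of how well calls held. Depth limits the rare miRNAs most, since 3 reads are 1.54 RPM in the smallest library and 0.244 in the largest, and with 2 libraries per group most 4-fold and 16-fold changes would have been missed.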

Other observations

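No test was run for this part, whose values were chosen after the data were seen.

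TAS loci also gave 24-nt reads, which stood highest in rdr2 although that genotype has few 24-nt reads in all. In flowers, they stood at 571 ± 328 RPM in wild type, 15.6 ± 3.17 in dcl1-7, 29.2 ± 22.4 in dcl234 and 2462 ± 1689 in rdr2 (mean ± SD, n = 2 each), beside 3169, 615, 403 and 34429 RPM of 21-nt reads from all TAS loci. Nuclear loci outside rRNA, tRNA, MIR and TAS genes gave 24-nt reads at 458966 ± 48523 RPM in wild type, 404989 ± 53429 in dcl1-7, 28911 ± 16801 in dcl234 and 17511 ± 2868 in rdr2. Their 21-nt reads stood at 21615 ± 15413, 30720 ± 7161, 138260 ± 57489 and 33459 ± 6834 RPM, so that dcl234 held the most, with both of its libraries above every library of the other genotypes. All RPM values here move with the share of the 24-nt class, which is small in dcl234 and rdr2.

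Among their length variants, most of the abundant miRNAs were read mainly as exact annotated sequences. Length variants share their first bases, so forms that start at another base were not counted. Counted were 26 miRNAs, or sets of miRNAs with the same start, with at least 1000 reads of length variants in at least 10 libraries. For a set, such as miR396a and miR396b, the reads of all its annotated sequences were added. Its share is therefore not that of a single sequence. Of the 26, 22 had a median of at least 90% of their length-variant reads with an exact annotated sequence. The medians ranged from 78.5% for miR161.1 to 97.7% for miR169d-g. In the control library of the wild-type submergence pair the share was lower, at 20.8% for miR158a (median over libraries 94.4%) and 52.2% for miR156a-f (median 94.8%).

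Untreated seedling library 3, which shares the low genome match of the phosphate-starved library, held 539 RPM of miR156a-f and 1905 RPM of miR157a-c. The untreated wild-type flower libraries held 12.9% and 3.78% of 21-nt reads.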
